A study of Mus musculus with 3 samples.

How the data were processed

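The series holds 3 mouse samples from the main olfactory epithelium of animals aged 4 weeks, per the labels. 2 are RNA libraries from sorted cells and are analysed here. The mOSN library came from cells positive for EGFP expressed with the olfactory marker protein gene Omp, in C57BL/6J mice. The O/Tet3 library came from mice in which a driver at Omp (OMP-tTA) switches on a Tet3-GFP transgene, in strain FVB. The remaining sample, DNA of O/Tet3 mice immunoprecipitated with an antibody to 5-hydroxymethylcytosine, is not analysed here. Per the labels' protocols, total RNA of the sorted cells was depleted of ribosomal RNA with the RiboMinus kit, made into libraries with the ScriptSeq kit, and amplified by PCR.

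The submitters' processing notes name Bowtie, Bowtie2, Cuffdiff and genome build mm9, without versions or roles. The gene annotation is not given in the sources used here, and neither is the strand setting, so reads of overlapping genes, antisense partners and near-identical paralogs, among them olfactory receptors, could not be separated further. The authors' deposited table gives, for each of 34617 gene rows, a log2 value per library and the difference of the libraries. The deposited log2 values are log2(value + 1), as found from the file. The lowest value is exactly 0, and raising 2 to the value and subtracting 1 gave numbers of at most 6 significant digits in 99.4% of the mOSN values and 99.3% of the O/Tet3 values above 0.01 (relative tolerance 1e-09), as Cuffdiff prints FPKM. The linear unit is not named in the file, so these numbers are called values here. The deposited log2 ratio column equals the O/Tet3 column minus the mOSN column within 8.0e-14. The design had been written for the linear unit; the same log2(value + 1) ratio then follows from the deposited columns. The columns were assigned by their names, which abbreviate the genotypes, and the Tet3 values go with that assignment.

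Each group has 1 library, so no test between groups, p-value or replicate check was possible, and genotype, strain and library differ together. All differences describe these 2 libraries. Read counts are not in the file. Values of low genes moved in whole-number steps: over 3182 low genes the most frequent log2 ratio was 0.92, held by 199 rows where the median window held 6, which puts 1 read at a 1.89-fold larger value in the O/Tet3 library. For olfactory receptor genes 1 read was worth about 0.0264 in mOSN and 0.0501 in O/Tet3, or about 37.87 and 19.97 reads per unit of value. An exact 0 can be a failed estimate in such a table (Lars2, which every cell uses, is at 0 in mOSN), so a gene is said to be listed at 0 and no fold is given against it.

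Log2 ratios are O/Tet3 over mOSN on the log2(value + 1) scale, which understates differences of low genes. Folds are ratios of the values themselves. A row was compared if its value was at least 1 in either library, and was counted as higher or lower when the log2 ratio was at least 1 in size, a 2-fold difference of value + 1. For each gene list with at least 3 compared members, the median log2 ratio was given with a distribution-free 95% interval over genes where the list is large enough, and with its percentile among 10000 random lists of the same size matched in 20 bins of the mean log2 value. Where a bin held fewer other genes than members, random genes were drawn with replacement. Genes are not replicates, so interval and percentile describe these libraries only.

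The 22 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The lists were olfactory receptors, their pseudogenes, trace amine-associated receptors, vomeronasal receptors, clustered protocadherins, odorant signal transduction, axon guidance and sorting, immature neuron markers, progenitor and proliferation markers, sustentacular cell markers, basal, gland and microvillous cell markers, glia, blood and vessel markers, DNA methylation and demethylation machinery, heterochromatin and receptor choice regulators, immediate early genes, odor activity-dependent neuron genes, stress and unfolded protein response, replication-dependent histones, cytosolic ribosomal proteins, small RNAs, sex-linked transcripts, and genes known to differ between C57BL/6J and other strains. The named genes are Tet1, Tet2, Tet3 and Omp, the 12 genes with the largest and the 12 with the smallest log2 ratio among genes with a value of at least 5 in either library (without small RNAs, receptors and unnamed or clone-like symbols), the 4 highest and 4 lowest receptors by the same floor, and up to 4 members per list with the largest ratio in size. Some genes that this rule selects are not reported here. The small RNA exclusion was applied without regard to letter case and also covers names such as SNORD and mmu-mir. Lists of p53 targets, germline genes, oxidative phosphorylation genes, mitochondrial ribosomal proteins and guanylyl cyclase D neuron markers were added after the data had been examined.

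The alternatives were a pseudocount of 0.1, ratios centred on the median of all genes, a floor of 5 or of any value above 0, a 3-fold threshold, removal of small RNAs, receptors and rows listed at 0 in 1 library, other detection levels for receptors, and matching on the mOSN value. Ratios without pseudocount and a floor on the mean of the libraries were added after the data had been examined. The procedure was tested on simulated data drawn from the mOSN values of all 34617 rows at both values of 1 read. The simulation holds counting error and a small fixed gene noise, and no variation between animals or preparations. The procedure called 100 of 100 genes set 4-fold higher, 100 of 100 set 4-fold lower and 0 of 11509 compared rows left unaltered. It put a list of 20 genes set 2-fold higher at percentile 100 and an unaltered list of 20 at 50.5. The altered genes and both lists were drawn at mOSN values of at least 5, so recovery at lower values was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. No genome of build mm9 was used, so no coordinates are given.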

Results

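Transcript levels were measured in sorted mature olfactory sensory neurons (mOSN library) and in sorted cells of mice that overexpress Tet3, an enzyme that oxidises 5-methylcytosine to 5-hydroxymethylcytosine, under the olfactory marker protein driver (O/Tet3 library). Each group has 1 library from 4-week-old mice, and the libraries also differ in strain (C57BL/6J and FVB). Of 34617 gene rows, 21218 were above 0 in mOSN and 19433 in O/Tet3, and 11350 and 11527 had a value of at least 1. The 6 largest rows took 90.05% of the summed values in mOSN and 96.9% in O/Tet3. There the row named Mir5105, listed at 0 in mOSN, took 68.6% alone. A value this large may not reflect the abundance of a microRNA, and its source was not tested. One read was worth a 1.89-fold larger value in the O/Tet3 library, so that a given value there rests on fewer reads; the total read depth is not in the file.

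The first question was whether the transgene is seen in the O/Tet3 library. Tet3 had a value of 3.72 in mOSN and 145 in O/Tet3, 39.1-fold higher (log2 ratio 4.95). Tet1 was at 2.98 and 8.37, and Tet2 at 4.03 in O/Tet3 against 2.11 in mOSN. Omp, whose locus drives the reporter or the transgene, was at 298 in mOSN and 139 in O/Tet3 (log2 ratio −1.09). Of the 20 compared members of the DNA methylation and demethylation machinery, 4 were at least 2-fold higher and 0 lower, against 2135 of all 12943 compared rows higher. Tet3 itself was 1 of the 4 and entered the list median, a log2 ratio of 0.56 at percentile 94.5 of matched random lists. The other higher members were Idh1, an isocitrate dehydrogenase that makes the 2-oxoglutarate Tet enzymes need, at 1.68 and 19.102, Tet1, and Gadd45b at 0.319 and 1.70.

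The second question was which transcripts differ between neurons with and without Tet3 overexpression. Odorant receptors and the genes that carry the odorant signal were lower in the O/Tet3 library, and ribosomal protein genes were higher. Among 12943 compared rows, 2135 were at least 2-fold higher and 1552 at least 2-fold lower in O/Tet3, and 445 of the lower rows were olfactory receptors. These and all list counts are at 2-fold of value + 1. A compared row listed at 0 in 1 library is called by construction, as were 184 of the higher and 482 of the lower rows. The median log2 ratio over the 9934 rows with a value of at least 1 in both libraries was 0.21. After this shift was subtracted, 1464 rows were higher and 1953 lower, so that the higher rows made up 42.8% of all called rows in place of 57.9%. The Pearson correlation of log2 values across compared rows was 0.75, which is across genes and not replicates.

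**Figure D1:**
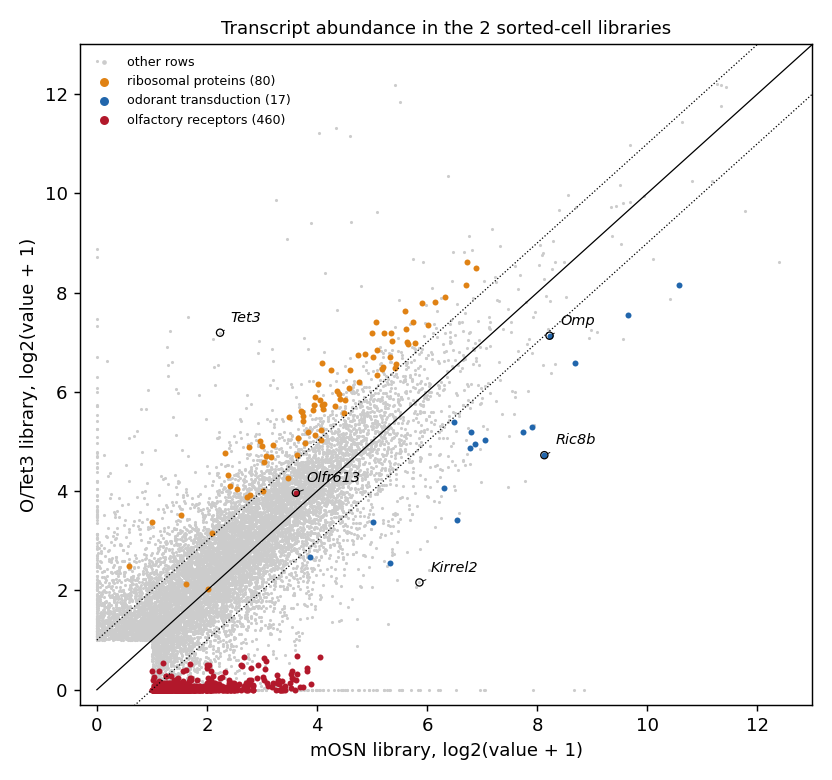
Log2(value + 1) of each compared gene row in the mOSN library (x axis) and the O/Tet3 library (y axis). The solid line marks equal values and the dotted lines a 2-fold difference of value + 1; the axes end at 13, and rows with larger values are not drawn. The 460 compared olfactory receptors lie near 0 on the y axis except Olfr613, the 17 odorant transduction genes lie below the lower dotted line, and 75 of the 80 ribosomal proteins lie above the upper one.

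Olfactory receptors, of which each mature neuron expresses mainly 1, were nearly all lower in the O/Tet3 library. Of 1096 receptor genes, 460 had a value of at least 1 in mOSN and 1 in O/Tet3. That receptor, Olfr613, was at 11.3 in mOSN and 14.6 in O/Tet3, while the next highest in O/Tet3, Olfr1226, reached 0.608 (named after its value was seen). The summed receptor value was 1607 in mOSN and 46.0 in O/Tet3, 34.9-fold lower, or 50.8-fold lower without Olfr613. These sums take receptors listed at 0 as 0, though a 0 can be a failed estimate. Of the 1096 receptors, 1001 were above 0 in mOSN and 274 in O/Tet3. Olfr166 was at 13.7 and 0.0893, Olfr131 at 12.4 and 0.0450, Olfr1262 at 12.0 and 0.0429, and Olfr31 at 11.1 in mOSN and listed at 0 in O/Tet3. Among receptors with a value of at least 5 in either library, Olfr1420, Olfr370 and Olfr609 had the highest log2 ratios after Olfr613 and were 9.36-fold, 12.2-fold and 13.4-fold lower. Of the 65 receptors with a value of at least 5 in mOSN, 14 were listed at 0 in O/Tet3, and 49 of the other 51 were at least 10-fold lower.

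The median log2 ratio of the 460 receptors was −1.53 (95% interval over genes −1.60 to −1.48), at percentile 0 of matched random lists, and 445 were at least 2-fold lower. Of the 460, 459 passed the floor only through mOSN. The 276 listed at 0 in O/Tet3 are called lower by construction and are among the 445. The SD of the log2 ratios of the 460 was 0.66, at percentile 0, against a median SD of 0.99 in the random lists, but at percentile 100 with no floor, so it does not rank receptors against other genes. Since 276 of them were listed at 0 in O/Tet3, the ratio mostly follows the mOSN level: the median was −4.11 with a pseudocount of 0.1 and −0.90 with no floor. The 10 highest receptors held 7.79% of the summed receptor value in mOSN and 41.6% in O/Tet3, where Olfr613 alone held 31.8%. All 23 compared receptor pseudogenes were at least 2-fold lower (median −1.75, percentile 0), among them Olfr1192-ps1 at 6.91 and 0.0509, Olfr1096-ps1 at 6.80 and 0.0994, Olfr1326-ps1 at 5.95 and 0.101, and Olfr721-ps1 at 5.63 and listed at 0. Their median value in O/Tet3 was 0. Pseudogenes listed at 0 there were compared through mOSN alone and are called lower by construction. Taar6, the only trace amine-associated receptor compared, was at 1.62 and listed at 0. The 2 vomeronasal receptors compared were at closer values, Vmn1r58 at 9.68 and 7.08 and Vmn2r55 at 2.26 and 2.45.

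The odorant transduction genes were lower as a group. All 17 compared members were at least 2-fold lower, with a median log2 ratio of −2.10 (95% interval −2.55 to −1.63) at percentile 0. Ric8b, an exchange factor for the olfactory G protein, was at 279 and 25.4. Gng13, a G protein gamma subunit, was at 91.9 and 9.63. The exchanger Slc24a4 was at 39.3 and 4.87, and the cyclic nucleotide-gated channel subunit Cnga2 at 238 and 37.9. The folds of the 17 genes ran from 2.14, for Omp, to 10.96, with a median of 4.31.

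Many axon guidance and sorting genes were lower. Of 25 compared guidance genes, 14 were at least 2-fold lower and 3 higher (median −1.03, percentile 0). The adhesion molecule Kirrel2 was at 57.1 and 3.47, the semaphorin Sema7a at 25.6 and 0.854, and the receptor Plxna1 at 23.7 and 2.53, while Sema3a was higher, at 0.902 and 6.83. Among 9 activity-dependent genes, which include Kirrel2, 4 were lower, 4 within 2-fold of value + 1 and 1 higher (median −1.0, 95% interval −3.31 to 0.80, percentile 0.40). S100a5 was at 1356 and 235, Lrrc3b at 25.6 and 1.68, and Calb2, encoding calretinin, higher at 39.7 and 108. Among 11 immediate early genes, Btg2 at 3.29 and 17.5 and Junb at 1.59 and 5.49 were higher, and Jun at 22.8 and 8.02 was lower (median −0.06, percentile 16.5).

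Of 25 heterochromatin and receptor choice regulators, 6 were at least 2-fold lower and 3 higher, with a median of −0.24 at percentile 0.49, or 11.04 when random lists were matched on the mOSN value. The lower members included the transcription factors Atf5 at 93.7 and 20.6, Ebf3 at 60.9 and 16.2 and Lhx2 at 35.9 and 9.27, and the adenylyl cyclase Adcy3 at 115 and 29.7, which is also in the transduction list. Of 18 clustered protocadherins, Pcdhb1 was lower at 99.3 and 23.8 and 0 were higher; Pcdhb11 was at 1.05 and 2.72. Their median of 0.32, at percentile 70.7, became −0.16 with a floor of 5.

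Cytosolic ribosomal protein genes were higher together. Of 80 compared, 75 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.64 (95% interval 1.49 to 1.71) at percentile 100, or 1.44 after the shift of all genes was subtracted. Rps13 was at 16.0 and 94.4, and Rpl36 at 4.04 and 26.2. Of 37 genes listed as replication-dependent histones, 14 were higher and 1 lower (median 0.72, percentile 99.9). Hist1h1c was at 9.06 and 34.5, Hist1h4j at 0.605 and 4.48, and the lower listed gene was Hist2h2be, at 176 and 16.1. Whether Hist2h2be depends on replication was not tested here. Of 17 stress and unfolded protein response genes, 7 were higher and 2 lower (median 0.39, percentile 68.5), with the heat shock genes Hspa1b at 1.19 and 14.2 and Hspa1a at 0.725 and 8.44, Creld2 at 4.63 and 18.9, and Xbp1 at 5.95 and 20.9.

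Markers of other cells of the epithelium moved less or in both directions. Of 14 immature neuron markers, 4 were higher and 2 lower (median 0.57, 95% interval −0.86 to 2.21, percentile 91.4). Gap43 was at 6.41 and 34.8, Stmn1 at 6.72 and 34.7, Sox11 at 0.383 and 6.05, and Dpysl5 lower at 7.98 and 1.46. The 4 compared progenitor markers were all within 2-fold of value + 1 (median 0.58, percentile 84.3), with Pcna at 18.4 and 33.1 and Kit at 0.741 and 1.73, 2.34-fold higher in its values. Of 7 sustentacular markers, 1 was lower, Ugt2a1 at 15.6 and 2.53, and 0 were higher (median −0.49, percentile 2.96). Of 7 glia, blood and vessel markers, 1 was lower, Fabp7 at 4.78 and 0.0607, and the hemoglobin gene Hba-a2 was at 39.9 and 21.0 (median −0.57, percentile 6.65). Of the 3 basal, gland and microvillous markers, Ascl3 at 1.58 and Cftr at 1.02 in mOSN were listed at 0 in O/Tet3, and Pou2f3 was at 0.582 and 2.90 (median −1.01, percentile 25.6). That percentile was 0.91 when random lists were matched on the mOSN value, and the median was −0.07 with no floor.

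**Figure D2:**
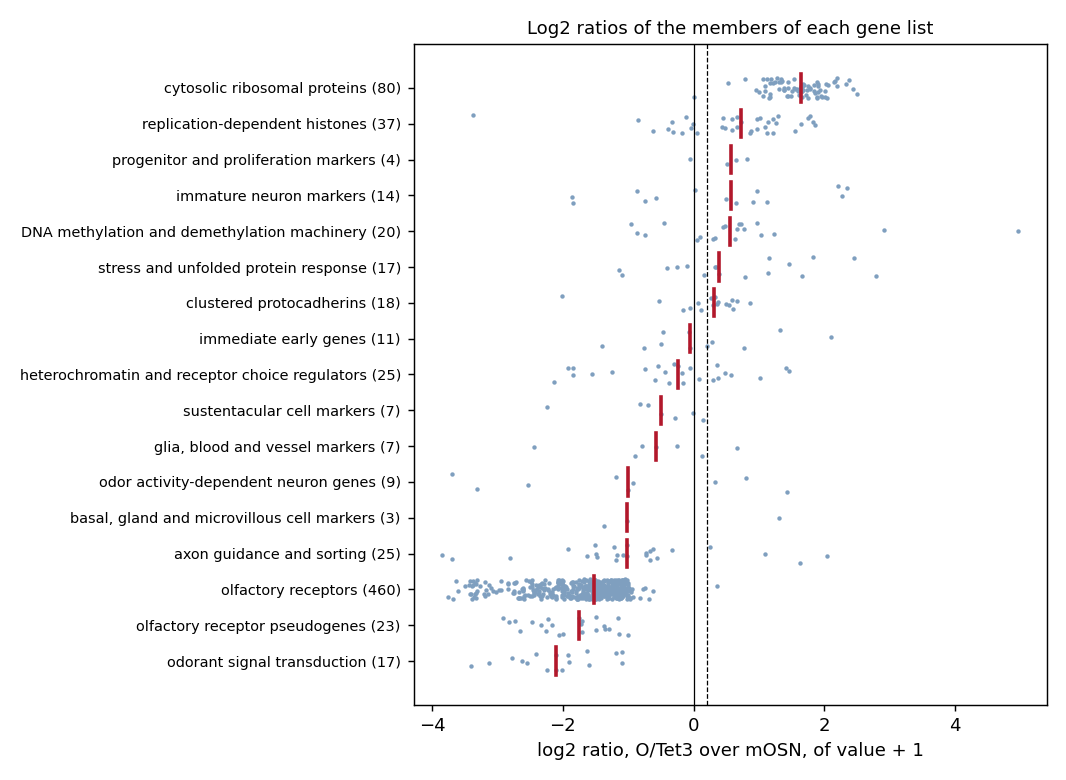
Log2 ratio of value + 1, O/Tet3 over mOSN (x axis), of each compared member (points) of 17 gene lists, with the number of members in parentheses and the list median as a red bar. The solid line is at 0 and the dashed line at 0.21, the median of rows with a value of at least 1 in both libraries. The medians run from −2.10 for odorant transduction to 1.64 for ribosomal proteins; points are spread vertically at random for legibility.

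Among the 12 genes with the highest log2 ratios by the rule for named genes were Dazl, a germ cell RNA-binding protein, at 0.135 and 97.1, and the meiotic recombination gene Mnd1, listed at 0 in mOSN and at 41.9 in O/Tet3. The flavin monooxygenase Fmo1 was at 3.30 and 133, Slco1a6 at 1.497 and 149, Crip1 at 0.852 and 49.2, and Camk2n1, an inhibitor of calmodulin kinase II, at 1.72 and 65.8. Lars2 (listed at 0 in mOSN, 6489 in O/Tet3), Ccrn4l (23.2 and 2262), Slc38a6 (44.4 and 3652), Kif24 (9.91 and 538) and Wdr31 (23.4 and 682) completed the highest genes beside Tet3. In O/Tet3 each of these exceeded Omp, at 139. Whether such values come from transcripts of these genes was not tested. Among the 12 lowest were Dnm1, encoding dynamin 1, at 64.4 and 4.34, and Cplx2, encoding a complexin, at 20.7 and 1.66. Lpcat4 was at 38.1 and 1.51, Ttll6 at 54.4 and 3.17, and Lypd2 at 12.5 and listed at 0; others were named with their lists.

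Of the sex-linked transcripts, Xist differed and the Y-linked genes were within 2-fold. Xist, expressed in females, was at 0.0137 in mOSN and 5.79 in O/Tet3, while the Y-linked genes Ddx3y, Uty and Kdm5d were at 4.09 and 5.54, 8.57 and 9.28, and 3.94 and 3.66 (list median 0.10, percentile 37.8, −0.10 after the shift of all genes was subtracted). All 4 compared genes known to differ between strains were within 2-fold of value + 1 (median 0.32, percentile 64.9), but in their low values Apobec3, at 0.511 and 1.97, was 3.85-fold and Hc, at 0.244 and 1.02, 4.18-fold higher. Of 66 small RNAs, 31 were higher and 20 lower (median 0.77, percentile 100), and several were listed at 0 in 1 library, such as Mir5105 at 5888970 and Snord85 at 470 in O/Tet3 and Snord21 at 241 in mOSN. With 1 library per group, no difference has a replicate check, and strain, genotype and the level of Xist differ together in each of them.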

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

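Of the alternatives here, ratios without pseudocount and a floor on the mean of the libraries were chosen after seeing the data. Under the alternatives, 96 values of the main results lay within 1.5 times a reported count or the interval of a reported median or percentile. For lists too small for an interval, the range of members was used. Another 28 did not, among them the centred sex-linked median, which had the opposite sign. The Tet3 log2 ratio was counted as moved at any difference, so both its alternatives are among the 28. For 1 further median, that of clustered protocadherins, the interval excluded 0 and the value lay outside it with the opposite sign. These bounds are wide for small lists: with no floor, the median became −0.07 for basal, gland and microvillous markers and 0.07 for progenitor markers. The Tet3 log2 ratio was 4.75 after centring on the median of all genes and 5.25 with a pseudocount of 0.1. Counts of higher and lower rows were 745 and 673 at 3-fold, 1401 and 793 with a floor of 5, and 1116 and 585 with a mean of at least 5. They were 3025 and 2025 with a pseudocount of 0.1. Without small RNAs, receptors and rows listed at 0 in 1 library they were 1897 and 888. A stricter fold or floor counts fewer rows by construction. With no floor both counts stay the same by construction, since a 2-fold difference of value + 1 needs a value of at least 1. Those unaltered counts are among the 96 values. Receptors with a value of at least 0.1 numbered 942 in mOSN and 95 in O/Tet3, and 65 reached 5 in mOSN. The receptor median was −2.94 with a floor of 5, −1.73 centred, −0.90 with no floor, −5.26 with no pseudocount, −4.11 with a pseudocount of 0.1 and −1.81 without rows listed at 0 in 1 library, negative in each. Its SD moved from percentile 0 to 100 with no floor and to 4.53 without rows listed at 0. The pseudogene median was −2.69 with a floor of 5, −0.32 with no floor, −4.46 with a pseudocount of 0.1 and −2.30 without rows listed at 0. The ribosomal protein median was 1.44 centred. With a pseudocount of 0.1 the median was −3.48 for basal, gland and microvillous markers and 0.87 for progenitor markers. 4 medians changed sign. Clustered protocadherins went from 0.32 to −0.16 with a floor of 5, and sex-linked from 0.10 to −0.10 when centred. Centring subtracts 0.21 from every ratio, so a median between 0 and 0.21 changes sign by construction. With no floor, immediate early genes went from −0.06 to 0.08 and strain genes from 0.32 to −0.03. Apart from centring, the cause was not tested for the list and receptor medians. Among single genes and percentiles, 33 values moved by at least 1 in log2 ratio or into or out of the outer 5% of the random lists, and 232 did not. The 232 include every centred ratio and percentile, which could not move by this rule. Centring shifts each single-gene ratio by 0.21 and shifts the random lists alike. Matched on the mOSN value, the percentile was 0.91 for basal, gland and microvillous markers, 2.24 for glia, blood and vessel markers, 11.04 for heterochromatin regulators and 97.4 for histones. Fewer reads per unit of value in the O/Tet3 library limit what can be said of receptors near the value of 1 read, 0.0501. No paired analysis was possible because each group has 1 library.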

Other observations

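The 4 tests on receptors and ribosomal proteins were chosen after the results were seen. The lists of p53 targets and germline genes were prompted by members already seen, and their bounds were set before the values of the other members were looked at.

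The lists set beside the ribosomal proteins also had higher medians in the O/Tet3 library. Of 76 oxidative phosphorylation genes, 22 were at least 2-fold higher (median log2 ratio 0.70, 95% interval over genes 0.56 to 0.81, percentile 99.97 of matched random lists). Of 76 mitochondrial ribosomal protein genes, 22 were higher (median 0.70, 95% interval 0.57 to 0.84, percentile 100). Both lists were chosen after the ribosomal protein result was seen.

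The summed receptor value was 34.9-fold lower in O/Tet3; read depth alone leaves scaled values within counting error, but 50 (98.04%) of the 51 receptors at 5 or more in mOSN and above 0 in O/Tet3 lay below the 95% Poisson interval of the reads expected at 19.97 reads per unit (median 152 expected, 2.95 seen). A smaller share of mature neurons as the whole cause would lower the receptors and the transduction genes alike. The transduction genes include Omp, 2.14-fold lower, whose locus also drives the reporter or the transgene. The receptor fold, however, was 8.10 times the median transduction fold and above the largest of these folds, 10.96. That receptor fold takes receptors listed at 0 in O/Tet3 as 0, so it rests partly on values that may be failed estimates. Over the 51 receptors compared for read depth, none of them listed at 0, 8564 reads were expected and 483 seen. Markers of other cells went both ways. Medians were 0.57 for immature neurons, whose 95% interval (−0.86 to 2.21) includes 0, and 0.58 for progenitors, or 0.07 with no floor. They were −0.49 for sustentacular cells and −0.57 for glia, blood and vessels, whose 95% intervals (−2.23 to 0.14 and −2.45 to 0.66) include 0. Guanylyl cyclase D neurons, which express no olfactory receptor, would bring Gucy2d, which was at 0.0852 in mOSN and 0.0123 in O/Tet3. Of their other markers, Cnga3, at 0.0564 and 1.42, and Pde2a, at 0.112 and 0.793, were higher in O/Tet3. Car2 was at 7.79 and 7.26. An effect of Tet3 overexpression on receptor transcription may be involved. But strain, the sex mix of the animals, FVB sequence differences from the reference and the lone library per group stay open. A smaller share of mature neurons as part of the cause stays open too, since the transduction folds themselves ran from 2.14 to 10.96. Of 14 immature neuron markers, 4 were at least 2-fold higher, among them Gap43, Stmn1 and Sox11, and 2 were lower. For the sex mix, Xist was at 0.0137 and 5.79, while the Y-linked Ddx3y, Uty and Kdm5d were within 2-fold.

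The ribosomal protein genes had a median log2 ratio of 1.64 (95% interval 1.49 to 1.71). A bias towards short transcripts could be the cause. Oxidative phosphorylation and mitochondrial ribosomal protein genes, compared as further lists of presumably short transcripts, lay below that interval, and the larger of their medians was 0.70. Transcript lengths were not measured here, so this does not exclude the bias, and strain, sex mix, genotype and library preparation stay open too.

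A hypothesis drawn from members already seen, such as Cdkn1a (7.81 in mOSN, 41.9 in O/Tet3), Ccng1 (13.3 and 116) and Eda2r (0.232 and 7.54), is that p53 targets are higher as a class. Among 24 compared members not looked at before, 12 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.03 at percentile 99.98, above the bound of 95. Rps27l had been seen with the ribosomal proteins and was moved out of this group after the first run; with it the median was 1.18 at percentile 100. Members include Trp53inp1 at 1.96 and 13.7, Plk2 at 0.285 and 4.95, Psrc1 at 0.235 and 6.53 and Aen at 2.82 and 11.5, while Ddb2 was at 4.95 and 4.41 and Bcl2l1 at 14.2 and 11.4. Btg2, Sesn2 and Rps27l are also in other lists. A member below 1 in mOSN, such as Plk2 or Psrc1, was compared only through O/Tet3 and could not be called lower. Members below 1 in both libraries were not compared. Of all 12943 compared rows, 2135 were at least 2-fold higher. p53 activity may differ between the libraries, but strain, genotype and possibly sex mix differ together and 1 library per group gives no replicate check.

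A second hypothesis, from Dazl, Mnd1, Tex19.1 (0.0263 and 6.88), Dpep3 (listed at 0 and 5.48) and Zcwpw1 (0.284 and 11.1), is that germline genes with methylated promoters gain transcripts as a class. Of 33 members not looked at before and below 1 in mOSN, 5 reached 1 in O/Tet3 (Tex14, Slc25a31, Sohlh2, Stra8 and Tex15), against a median of 2 in random lists, where 1593 of all 23267 such rows did. Fewer than 5 did so in 92.69% of random lists, below the bound of 95 set before. A first run had counted ties by 0.5, which gave 95.26%. The bound as written asks for more members than in 95% of lists and leaves ties out, and by that reading it was missed. The handling of ties was changed after the first result was seen, so the test leaves the hypothesis undecided. Most members stayed below 1, such as Sycp1 at 0.457, Ddx4 at 0.181 and Mael at 0.680 in O/Tet3.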
